A study of Oryza sativa with 8 samples.

How the data were processed

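Total RNA from roots and shoots of WT and mhz7 rice seedlings was hybridized to Affymetrix rice arrays as biotinylated cRNA, from 5 µg of RNA per sample, per the labels' protocols. Seeds germinated in the dark at 37 °C for 2 days and seedlings were kept at 28 °C, per the same protocols. The 8 arrays hold 1 sample for each combination of genotype, tissue and gas, so there are no replicates within a condition. No table of per-sample values was left out.

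The deposited values are intensity values, 1 per probe set and array on a linear scale, and MAS5 is the tool given in the submitters' processing notes. Its scaling target, its version and its detection calls are not given in the sources used here, so the scaling behind the values stays unknown. The deposited medians were 44.6 for WT root in air, 43.0 for WT root in ethylene, 42.9 and 43.1 for WT shoot in air and ethylene, 43.0 and 43.0 for mhz7 root, and 43.5 and 43.8 for mhz7 shoot. The trimmed means lay between 238.3 and 250.3. None of the values was at or below 0.

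Of 57381 probe sets, 123 controls were set aside and 57258 analysed. Each array was multiplied by a factor (2.00 to 2.10) that brought the mean of its values, without the highest and lowest 2%, to 500. Signals under a floor of 100, which held 51.5 to 53.1% of the probe sets of an array, were set to 100, and log2 was taken. Signals near the floor limit what small or weakly expressed transcripts can show, so a gene at the floor on 1 array is given as a bound ("at least"). Fold sizes were taken from the floored signals. Log2 differences are the first-named group minus the other.

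The array gene table gave 1 gene for 22436 probe sets, several for 95 and none for 34727, covering 17905 genes, and symbols came from the gene table of the ASM3414082v1 assembly (Oryza sativa Japonica Group), which was used for names only. Only 2452 genes carry a symbol beyond a locus number, so many genes are printed by locus. Where a gene had several probe sets, the brightest of those with a mean signal of at least 200 over the 8 arrays stands for it, unless another is the one tested. That minimum left 21444 probe sets and 13839 genes.

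For 2 arrays, a probe set counted as changed where the log2 difference was at least 1 in size and the higher signal at least 200. The share of WT ethylene changes seen in mhz7, and of root changes seen in shoot, was set against 10000 random sets matched on mean signal in 20 bins. Fits over 4 pairs used limma 3.58.1 in R 4.3.3 on the 21444 probe sets, with the pair as a block and 3 residual degrees of freedom, empirical Bayes variances and Benjamini-Hochberg adjustment at 0.05. The pairs come from the design and not from sample numbers: each is the 2 arrays that share the other factors. Other figures were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

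There were 26 gene lists, defined by symbol patterns, and 25 had enough measured genes for a median, giving 200 medians over the 8 comparisons of 2 arrays: ethylene perception and signalling, ethylene biosynthesis, ERF and DREB factors, cytokinin response regulators, cytokinin metabolism, auxin response, auxin biosynthesis, jasmonate, abscisic acid, type 2C phosphatases, gibberellin, expansins and wall-loosening enzymes, secretory peroxidases, germin-like proteins, photosynthesis, defence, diterpenoid phytoalexins, fermentation, cell cycle and histones, cytosolic ribosomal proteins, heat shock proteins, iron acquisition, nitrate and phosphate transport, phenylpropanoid enzymes, aquaporins, and seed storage. The groups, comparisons, tests, thresholds and first set of lists were chosen before the data were examined. The lists were restated as symbol patterns, and those of diterpenoid phytoalexins, aquaporins and type 2C phosphatases added or split off, once the gene tables showed only symbols and before any difference was computed. EBF and RTH genes and SUB1, RAP2.8 and RRA5 were looked for and not found by name.

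Genes named for a pair of arrays are drawn from the 8 largest rises and 8 largest falls measured on both arrays, overall and among genes with a symbol, up to 3 bounds in each direction, and up to 4 members of a list. For a fit they are the 5 with the smallest adjusted p in each direction. EIN2, the receptor genes, EIL1 genes, ACC oxidase genes and the array controls were always looked at. Naming by symbol was added before any difference was computed.

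The limma step was tested on simulated data for 21444 probe sets. Of 100 simulated changes it recovered 92 of log2 size 1 and 97 of size 2 for ethylene and 78 and 95 for genotype. For tissue it recovered 68 and 93, and for the interaction 1 and 95. False calls numbered 6, 12, 8 and 13, in that order. The spread was drawn from the distribution limma had fitted, with no floor, and each change was equal in all pairs. Recovery with unequal changes or floored signals is unknown. The 2-fold rule found 400 of 400 simulated 4-fold changes on 57258 probe sets, all placed in probe sets with a signal of at least 400 and little noise. Changes near 2-fold or near the floor were not simulated, so recovery at the threshold itself is unknown. In 200 draws of unshifted values for a random list of 30 genes, 6 medians fell outside the middle 95%. Values were drawn independently for each gene, so lists whose members vary together were not covered. Alternatives were floors of 50 and 200, quantile normalization, loess (span 0.4), a 3-fold threshold, 1 probe set per gene, no signal minimum, trend=TRUE, an adjusted p of 0.1, no pair block, each pair left out, and the mean of a gene's probe sets. After the data were seen, removal of probe sets at least 10-fold brighter in the other tissue was added.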

Results

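Transcript levels were measured on 8 Affymetrix rice arrays, 1 for each combination of genotype (wild type, WT, or the mhz7 mutant), tissue (root or shoot) and gas (air or ethylene). Ethylene is a gaseous plant hormone, and MHZ7 is listed in the gene table as a synonym of EIN2, which carries the ethylene signal downstream of the receptors. Dark-grown seedlings aged 3 days received 10 ppm ethylene for 8 h or stayed in air, and RNA came from roots and shoots separately. Each array gave a signal for 57258 probe sets, of which 20237 to 20547 read above 200 after scaling. With 1 array per condition, no difference between 2 arrays has a replicate check, and the number of arrays limits the precision of each value. A gene is said to have risen or fallen in such a pair where the difference was at least 2-fold and the higher signal at least 200.

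Root and shoot profiles were far apart, and genotype and gas moved them less. Arrays of the same tissue correlated across probe sets at r = 0.944 to 0.992, and arrays of different tissues at 0.665 to 0.708. Shoot-abundant transcripts were visible on the root arrays: 122 such probe sets stood at a median of 3.36% of their shoot signal in WT roots in air and 1.93% in ethylene, and at 1.69% and 0.918% in mhz7 roots. The 15 root-abundant probe sets followed on the shoot arrays stood at 3.71% and 1.76% in WT and at 3.16% and 0.936% in mhz7. These percents use signals without the floor. On the mhz7 ethylene arrays the median signals of these sets, 89.3 in root and 83.1 in shoot, lay under the floor of 100. The ratio of the 3′ to the 5′ actin control probe set, which increases as RNA is degraded, was 6.62 in WT roots in air, 6.80 in WT roots in ethylene, 6.34 and 8.26 in WT shoots, 6.81 and 9.32 in mhz7 roots, and 9.55 and 13.5 in mhz7 shoots.

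**Figure D1:**
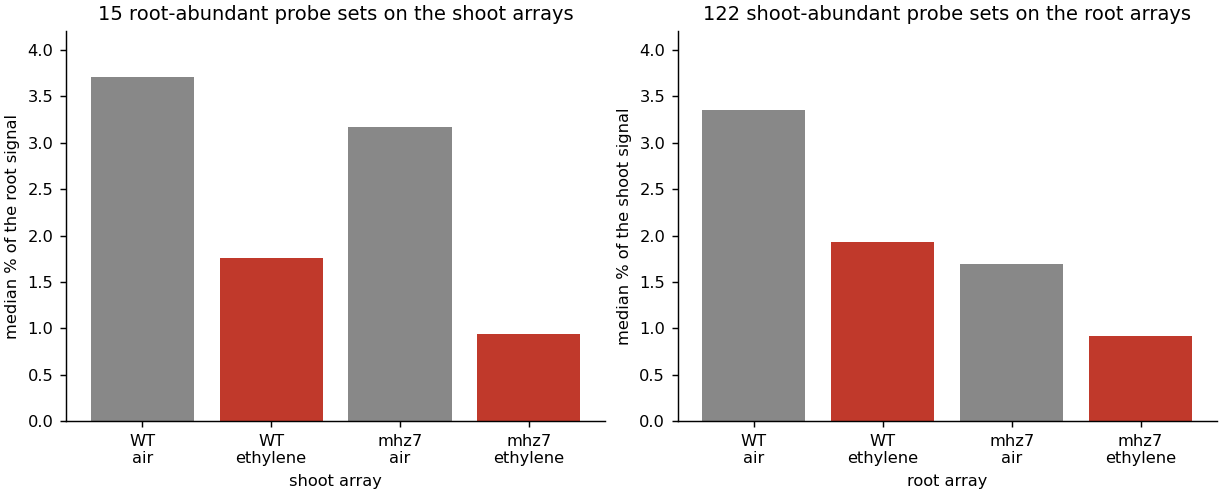
Signal of probe sets abundant in one tissue on each array of the other tissue, as a percent of their own-tissue signal. Each percent was taken against the own-tissue array of the same genotype and gas, and bars show the median over probe sets. Grey is air and red is ethylene. Root-abundant probe sets on shoot arrays are on the left, and shoot-abundant probe sets on root arrays on the right. In each genotype and tissue the ethylene array held the lower percent, from 3.71% down to 0.918% over the 8 arrays. The percents use signals without the floor, and on both mhz7 ethylene arrays the median signal was under the floor of 100.

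EIN2 itself was read at higher levels in mhz7 than in WT in each of the 4 tissue and gas conditions. Its scaled signal was 1649 in WT roots in air, 1064 in WT roots in ethylene, 859 in WT shoots in air and 747 in WT shoots in ethylene. In mhz7 the same conditions gave 2792, 2462, 1532 and 1574, and the limma fit over the 4 pairs put the mean difference at 0.97 on the log2 scale (SE 0.0967, adjusted p = 0.0348, higher in 4 of 4 pairs). The lesion of the mutant is not given in the sources used here, so the EIN2 level does not test the genotype label. Among the 7 measured genes of ethylene perception and signalling, the receptor gene ETR2 rose 2.58-fold with ethylene in WT roots. On the log2 scale, where 2-fold is 1, its ethylene change was 0.86 in WT shoots, 0.31 in mhz7 roots and 0.07 in mhz7 shoots. ETR2 stood below its WT level in mhz7, by 3.64-fold in roots in ethylene and 3.30-fold in shoots in ethylene. The receptor genes ERS1, ERS2 and ETR3 and the transcription factor gene EIL1A stayed within 2-fold in all 8 comparisons of gas or genotype. The median of this list lay outside the middle 95% of random lists in mhz7 against WT shoots in air (-0.37, percentile 0.02) and with ethylene in mhz7 shoots (0.13, percentile 97.72). EIL1B fell 4.04-fold with ethylene in WT shoots, from 617 to 152, and stood at 1437 and 1498 in mhz7 shoots. Of the ethylene synthesis genes, ACO1, which encodes an ACC oxidase and was over 10-fold brighter in shoots, fell with ethylene in mhz7 roots (-1.02) and was lower in mhz7 than in WT roots (-1.70 in air and -2.09 in ethylene). The S-adenosylmethionine synthetase genes SAM1 and SAM2 differed by no more than 0.29 in any comparison of gas or genotype.

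**Figure D2:**
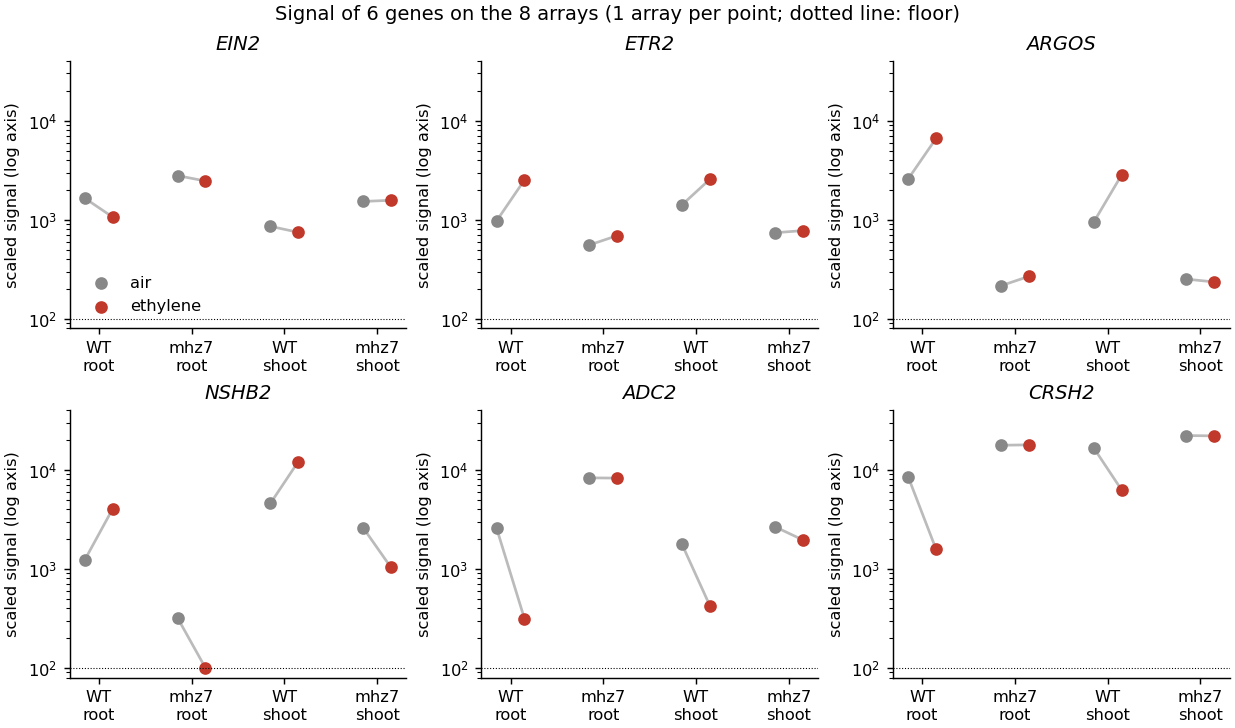
Scaled signal (log axis) of EIN2, ETR2, ARGOS, NSHB2, ADC2 and CRSH2 on the 8 arrays (1 array per point; grey, air; red, ethylene; grey lines join the air and ethylene arrays of a genotype and tissue; the dotted line is the floor of 100). ARGOS read 2591 and 6633 in WT roots and 216 and 268 in mhz7 roots.

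Ethylene against air in WT roots asks which transcripts differ with ethylene where MHZ7 is intact. Among probe sets with a gene listed, that of LOC4344999 rose most, 14.4-fold from 384 to 5517, and ADC2, which encodes arginine decarboxylase of polyamine synthesis, fell most, 8.16-fold from 2572 to 315. CRSH2, a (p)ppGpp synthetase gene, fell 5.36-fold from 8449 to 1576. In all, 234 probe sets rose and 225 fell, covering 299 genes. The next rises belonged to genes without a symbol: LOC4326518 (2.77), LOC4342313 (2.73), LOC9271323 (2.44), LOC107277424 (2.44), LOC4342528 (2.36) and LOC4325834 (2.33).

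Genes with a symbol that rose in WT roots included the lipoxygenase gene LOX3 (1.84), the non-symbiotic haemoglobin gene NSHB2 (1.71, from 1239 to 4050.0), the germin-like gene GLP2 (1.58), the homeobox gene WOX6 (1.54) and ARGOS, an organ-size gene (1.36). LOC4340245, listed as IAA20 and so placed with auxin response, rose by 2.11, and LOC4342614, listed as DXPS, by 2.07. Falls included LPR1 (-1.60), ROMT-17 (-1.54) and the laccase gene LAC10 (-1.38). CM-LOX1, at the floor in air, was at least 2.82-fold higher in ethylene.

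Of the 10 measured genes of diterpenoid phytoalexin synthesis, CPS4 (1.66) and CYP99A3 (1.62) rose in WT roots and CYP701A8 fell (-1.23). The list median was -0.25, at percentile 0.04 of 10000 random lists matched on mean signal, a description of these arrays and not a test. Fermentation and low oxygen genes had a median of 0.24 (percentile 99.97), with NSHB2 the member that rose and the alcohol dehydrogenase gene Adh2 at 0.66. Among 20 genes of abscisic acid synthesis and response, the dehydrin-type genes RAB21 (-1.58), RAB16D (-1.21) and RAB16C (-1.18) and LEA19 (-1.31) fell, and the list median was -0.06 (percentile 0.82). RAB21 is one of the genes over 10-fold brighter in shoots. EXP6 rose (1.44) against a median of -0.11 over the 22 expansins and wall-loosening enzymes (percentile 0.09). The median of the list photosynthesis and chlorophyll, ethylene minus air, WT root, was -0.39 (percentile 0), with RBCS (-1.90) and CAB2R (-1.22) the members that fell, but 0.0105 over the 3 genes left without probe sets over 10-fold brighter in shoots, a step chosen after seeing the data. RBCS, CAB2R, the lipid transfer protein gene LTP2-B (-1.95) and GER5 (-1.38) are over 10-fold brighter in shoots, and the shoot-abundant set stood at 3.36% of its shoot signal in air and 1.93% in ethylene. The 20 aquaporin genes had a median of -0.14 (percentile 0.03) with no member changed.

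In mhz7 roots, several of the leading WT genes differed little between ethylene and air. The log2 difference was 0.23 for LOC4344999, -0.01 for ADC2, 0.01 for CRSH2, 0.31 for ARGOS and -0.52 for GLP2. LOC4347709, over 10-fold brighter in shoots, fell in both genotypes (-2.32 in WT, -2.67 in mhz7), as did LTP2-B. The largest measured fall was that of PDC1, a pyruvate decarboxylase gene of ethanol fermentation, 9.84-fold from 1169 to 119. LOC4336402 had the largest rise, 5.98-fold from 264 to 1577. Rises numbered 71 probe sets and falls 194, over 164 genes.

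Further rises in mhz7 roots were those of LOC4332175 (1.69), LOC4347963 (1.65), MYB2 (1.40), the phenylalanine ammonia-lyase gene PAL06 (1.20), the tonoplast aquaporin gene TIP3-1 (1.14), NAC067 (1.11) and ABA8OX1, an abscisic acid catabolism gene (1.04). Falls included LOC4350217 (-2.62), LOC4349113 (-2.34), the nitrate transporter gene NRT2.2 (-1.60), the potassium transporter gene HAK16 (-1.46) and the metallothionein gene MT1B (-1.41). Of 10 diterpenoid phytoalexin genes, 6 fell, among them CPS4 (-1.68), CYP99A3 (-1.60), CYP701A8 (-1.39) and OsMAS (-1.29), and the median was -1.13 (percentile 0). CPS4 and CYP99A3 thus moved in opposite directions in the 2 genotypes. NSHB2, which rose in WT, was at least 3.19-fold lower in ethylene than in air. Iron acquisition genes had a median of -0.29 (percentile 0), with the transporter gene osysl15 the member that fell (-1.16), and nitrate and phosphate transport genes one of -0.18 (percentile 0.02), with NRT2.2, PHT1-2 (-1.10) and AMT3-3 (-1.03) lower. GER5 and LTP2-B, both over 10-fold brighter in shoots, were at least 7.09-fold and 4.69-fold lower on the ethylene array, on which the actin ratio was higher by 0.45 on the log2 scale.

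Of the 459 probe sets that changed with ethylene in WT roots, 59 (12.9%, 95% Wilson interval 10.1 to 16.2%, covering counting error only) changed the same way in mhz7 roots. Of the 234 rises 6.84% did so, and of the 225 falls 19.1%. Random sets matched on mean signal reached at most 2.18%. The share of the WT root ethylene changes seen in mhz7 root was 8.25% at 3-fold, below that interval, and 9.21% without probe sets over 10-fold brighter in shoots, a step chosen after seeing the data. The median mhz7 change of the 459, taken in the WT direction, was 0.06. Split by WT direction, the mhz7 median was 0 for the rises and -0.23 for the falls. With the genotypes exchanged, 22.3% of the 265 mhz7 changes were seen in WT, and their median was 0.44. Across 21444 probe sets, which are not independent replicates, the ethylene changes of WT and mhz7 roots correlated at r = 0.187.

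**Figure D3:**
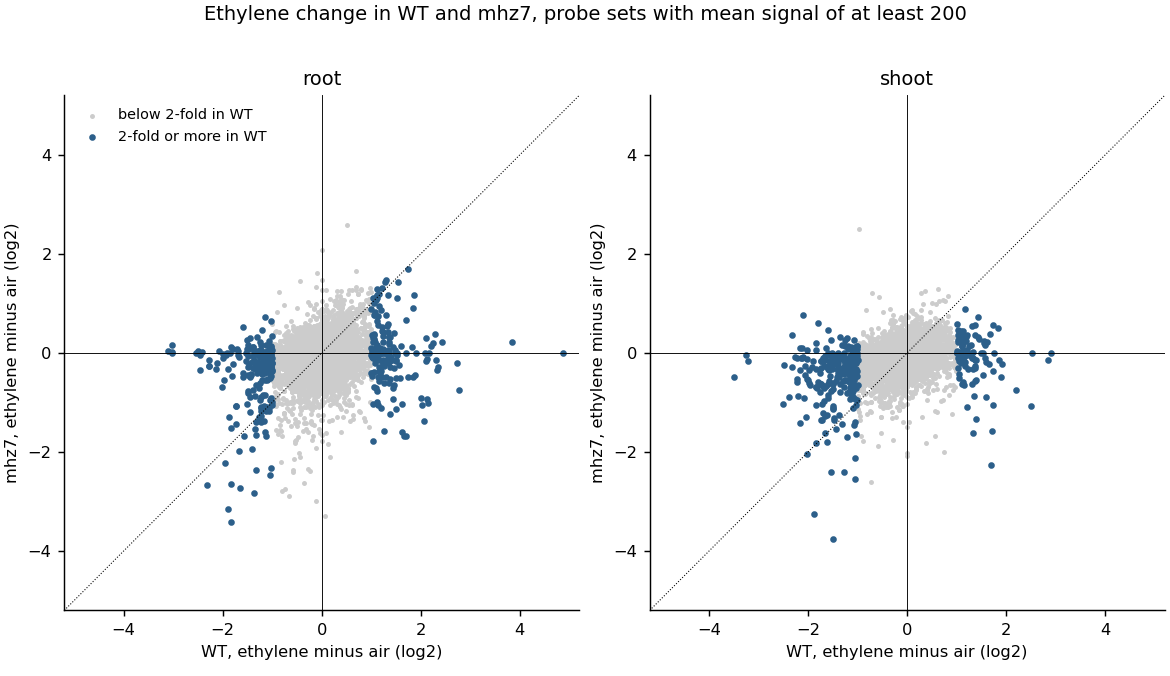
Ethylene minus air log2 difference in WT (horizontal axis) and mhz7 (vertical axis) for root (left) and shoot (right), 1 point per probe set with a mean signal of at least 200 (blue, changed at least 2-fold in WT; grey, not; the dotted line marks equal change). WT changes spread along the horizontal axis, with medians in mhz7 of 0.06 in root and 0.26 in shoot in the WT direction. The WT rises alone had a median of 0 in mhz7 in both tissues.

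In WT shoots, ethylene was followed by more falls than rises. PDC1 fell 9.26-fold from 1206 to 130.2, LOC4333794 fell 9.60-fold, and LOC4327002 rose 7.19-fold from 191 to 1376. Diterpenoid phytoalexin genes fell together: 7 of 10 did, with a median of -1.26 (percentile 0). Across the array 117 probe sets rose and 301 fell, over 281 genes. The actin ratio was higher on the ethylene array by 0.38 on the log2 scale.

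Genes with a symbol that rose in WT shoots included ARGOS (1.58), BU1, a helix-loop-helix gene (1.43), NSHB2 (1.40), the beta-expansin gene EXPB7 (1.33), BGLU3 (1.56), the chitinase gene Cht6 (1.33) and the ammonium transporter gene AMT3-3 (1.30). LOC4349327 rose 5.64-fold, and LOC4346629, at the floor in air, was at least 7.48-fold higher. ADC2 (-2.06), CRSH2 (-1.41), the pyruvate phosphate dikinase gene PPDKB (-2.07), PMEI8 (-1.84) and LOC4350823 (-2.51) fell, and the alpha-amylase gene AMY1.1 was at least 6.21-fold lower. The diterpenoid genes that fell included CYP71Z7 (-1.99), CYP99A3 (-1.69), CYP701A8 (-1.67) and OsMAS (-1.39). Of 20 defence genes, 4 fell, among them PBZ1 (-1.73) and Cht9 (-1.31), and Cht6 rose. The 39 cell cycle and histone genes had a median of -0.21 (percentile 0) with none changed 2-fold, as with RPA1B (-0.55) and CDC2Os-3 (-0.49). JAZ8 (-1.49) and OPR10 (-1.11) were the jasmonate genes that fell, and that list's median was -0.14 (percentile 0). Photosynthesis genes had a median of -0.29 (percentile 0) and phenylpropanoid enzymes one of -0.17 (percentile 0.11), with CAD6 lower (-1.14). The aquaporin genes TIP2-1 (-1.49), which is over 10-fold brighter in roots, TIP1-2 (-1.13) and PIP2-7 (-1.44) fell, as the root-abundant set went from 3.71% to 1.76% of its root signal.

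In mhz7 shoots, 16 probe sets rose with ethylene and 114 fell, over 87 genes. LOC4340818 rose 5.64-fold, the lipoxygenase gene LOX1.1 2.32-fold from 5205 to 12050.2, PGIP-1, a polygalacturonase inhibitor gene, 2.21-fold, and JAZ13 2.01-fold. RAB16D fell 3.53-fold from 1032 to 293 and OsPP2C45 3.38-fold. Several of the largest falls belonged to root-abundant transcripts, including the aquaporin gene TIP2-1, which was at least 13.5-fold lower.

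Other rises in mhz7 shoots were those of GRXC10 (1.15), LOC4331849 (1.26) and LOC4326757 (1.25), and other falls those of LAC24 (-1.43), CM-LOX2 (-1.38), LAC19 (-1.37), LOC4342395 (-1.99) and NSHB2 (-1.33). LOC4331301 (-3.26), LOC4349200 (-1.88), MT4A (-1.44), PIP2-4 (-1.39) and the nicotianamine synthase genes NAS1 (-1.05) and NAS2 (-1.19) also fell. These 6 are over 10-fold brighter in roots, and the root-abundant set went from 3.16% to 0.936% of its root signal. Several genes among the WT shoot changes stayed within 2-fold, with ARGOS at -0.09, BU1 at 0.73, ADC2 at -0.44, PDC1 at -0.17 and EIL1B at 0.06. No diterpenoid phytoalexin gene fell 2-fold, although the list median was -0.61 (percentile 0). Medians of -0.25 for defence genes and -0.20 for photosynthesis genes (both at percentile 0) came with 1 changed member, RCABP89 (-1.09), a chlorophyll a/b-binding protein gene. The actin ratio was higher on the ethylene array by 0.50 on the log2 scale.

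Of the 418 probe sets that changed with ethylene in WT shoots, 40 (9.57%, Wilson interval 7.11 to 12.8%) changed the same way in mhz7 shoots, 0.855% of the 117 rises and 13.0% of the 301 falls. Random sets reached at most 1.91%, and the median change in the WT direction was 0.26. Split by WT direction, the mhz7 median was 0 for the rises and -0.38 for the falls. Exchanging the genotypes gave 30.8% of the 130 mhz7 changes and a median of 0.53. Leaving out probe sets over 10-fold brighter in roots, a step chosen after seeing the data, lowered the share from 9.57% to 4.72%. The share of the WT shoot ethylene changes seen in mhz7 shoot was also lower at 3-fold (4.42%), with a floor of 200 (5.71%) and with 1 probe set per gene (7.08%).

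Root and shoot of WT can be set side by side with no array in common. LOC4344999 rose in both tissues (3.84 in root, 1.68 in shoot), as did ARGOS, NSHB2 and GLP2 (1.09 in shoot), and ADC2 and CRSH2 fell in both. CYP99A3 and CPS4 moved apart, with 1.62 and 1.66 in root and -1.69 and -1.14 in shoot. Of the 459 root changes, 67 (14.6%, Wilson interval 11.7 to 18.1%) were seen in shoot in the same direction, against at most 2.83% in random sets. At 3-fold the share of the WT root ethylene changes seen in WT shoot was 10.3%. Starting from the 418 shoot changes the share was 16.0%, and r across probe sets was 0.210.

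Comparing mhz7 with WT asks what the mutation alters, first in roots. In air, the JAZ-type genes TIFY11A and JAZ13, whose products repress jasmonate responses, stood 10.3-fold and 8.90-fold above WT, PDC1 stood 8.14-fold above, and ARGOS stood below WT (-3.58). In ethylene, ADC2 stood 26.2-fold above WT (8248 against 315), CRSH2 11.3-fold above and LOC4344999 36.9-fold below. The WT root ethylene array behind these values is the one in which ADC2 and CRSH2 fell and LOC4344999 rose. In air 415 probe sets were higher in mhz7 roots and 368 lower (520 genes), and in ethylene 748 were higher and 1025 lower (1175 genes).

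Other genes above WT in mhz7 roots were the transcription factor genes BHLH148 (2.55 in air, 3.24 in ethylene) and WRKY71 (2.10, 2.26), LOC4335417 (4.01, 4.90), LOC4346787 (3.40, 4.07), CML15 (2.46 in air) and LOC9268308 (5.07 in air). DREB1B and the glutamate dehydrogenase gene GDH2, both at the floor in WT in air, were at least 6.70-fold and 4.45-fold higher, and LOC4331398 at least 20.6-fold. Genes below WT included the ammonium transporter gene AMT1-2 (-2.99 in air), the cytosolic glutamine synthetase gene GLN1-2 (-2.21, -3.32), the heat shock gene HSP81-1 (-2.35, -2.73), Adh2 (-1.99, -2.62), LOC4332910 (-3.50, -5.07) and LOC4333735 (-2.86, -4.82). NSHB2 was lower in air (-1.96) and at least 40.5-fold lower in ethylene. In ethylene GSTU6 (-2.73), HSP23.2 (-2.88) and NRT2.2 (-2.68) were also lower.

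Among 27 jasmonate genes, 10 were higher in mhz7 roots in air and 10 in ethylene and 1 was lower in each gas, with medians of 0.56 and 0.61 (both at percentile 100). The 12 measured JAZ genes gave 8 rises in each gas and medians of 1.49 and 2.02. LOX1.1 was higher in both (1.33, 1.19). Iron acquisition genes were lower, 4 of 22 in air and 9 in ethylene, with medians of -0.54 and -0.73 (both at percentile 0): osysl15 stood at -1.60 and -2.34, osysl16 at -1.53 and -2.07, osysl9 at -1.22 and -1.44, and the nicotianamine synthase gene NAS3 at -1.22 and -1.43. Nitrate and phosphate transport genes had medians of -0.43 and -0.64 (percentile 0), AMT1-2 and NRT2.2 being the members that fell in both gases. Aquaporin medians were -0.24 and -0.23 (percentiles 0 and 0.05), with TIP1-2 (-1.84, -1.38) and PIP2-5 (-1.27, -1.36) lower and 1 gene higher in ethylene. Of the diterpenoid phytoalexin genes 3 of 10 were higher in air, among them CPS4 (1.20), with 6 above 0 and a median of 0.57 (percentile 100). In ethylene CPS4 (-2.13) and CYP99A3 (-2.53) were lower and the median was 0.02 (percentile 62.15). Defence genes had a median of 0.38 in air (percentile 100), with WRKY71, Cht2 (1.90) and PBZ1 (1.33) risen and CH6 fallen (-1.44), and one of -0.01 in ethylene (percentile 41.25). Cell cycle and histone genes had medians of 0.23 and 0.22 (percentile 100) with no member changed 2-fold. Of the 3 measured ERF and DREB genes, DREB1A and DREB1B were higher and EREBP-1 was at -0.11 in air. Photosynthesis genes had a median of -0.39 in air (percentile 0), where the shoot-abundant set stood at 3.36% in WT and 1.69% in mhz7. Fermentation and low oxygen genes had a median of -0.30 in ethylene (percentile 0.32), where 3 fell and none rose. Abscisic acid genes had one of -0.25 in air (percentile 0.03), with none changed 2-fold. The actin ratio of mhz7 roots exceeded that of WT by 0.04 in air and 0.45 in ethylene on the log2 scale.

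In shoots, PDC1 stood 4.60-fold above WT in air (5543 against 1206) and 37.9-fold above it in ethylene, and JAZ11 stood 4.17-fold and 4.83-fold above. The lipid transfer protein gene LTP-2 was 8.48-fold and 7.83-fold below WT, and BU1 3.97-fold and 6.45-fold below. In air 409 probe sets were higher and 258 lower (455 genes), and in ethylene 625 and 489 (754 genes).

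RAB16D (2.58), OsPP2C45 (2.11), LOC4344618 (4.05), LOC4344615 (3.59) and the pyruvate phosphate dikinase gene PPDK2 (2.22) led the higher genes in air, with LOC9268308 at least 26.1-fold higher. In ethylene, EIL1B (3.30), JAZ8 (3.12), PXG (2.97), PPDK2 (2.88), PPDKB (2.73), LOC4340892 (4.36) and LOC4333070 (3.81) were higher. Lower genes in air included the aluminium transporter gene Nrat1 (-2.35), PGIP-1 (-1.93), ARGOS (-1.91), the expansin gene EXP1 (-1.86), LOC4341714 (-2.81) and LOC4344999 (-2.70). In ethylene ARGOS (-3.58), NSHB2 (-3.54), LOC4342395 (-4.64), LOC4349327 (-4.27) and EXPB7 (-2.10) were lower. PIP2-4 (-2.79) and MT-1-4b (-3.31) were also lower there, both being over 10-fold brighter in roots.

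Jasmonate genes were higher in mhz7 shoots as well, 7 of 27 in air (median 0.31) and 10 in ethylene (median 0.61, both at percentile 100). Among them 7 of the 12 JAZ genes rose in each gas, with JAZ medians of 1.34 and 1.29, and LOX1.1 rose in ethylene (2.28). Diterpenoid phytoalexin genes were higher, 4 of 10 in air and 6 in ethylene, with medians of 0.78 and 1.51 (both at percentile 100): CYP71Z7 stood at 1.01 and 2.39, and CYP701A8 at 1.37 and 2.33. Defence genes had medians of 0.58 and 0.31 (percentiles 100 and 99.98), WRKY71 (1.20, 1.23) and Cht2 (1.55, 2.49, the latter a lower bound) being among those that rose. The cell cycle and histone medians were 0.14 and 0.31 (percentiles 99.99 and 100), with MCM3 at 0.32 and 0.55. Expansins and wall-loosening enzymes had a median of -0.16 in air (percentile 0.14). The iron acquisition medians, -0.04 and -0.07, lay inside the random range (percentiles 36.41 and 10.88), with 2 of 22 genes lower in air and 4 in ethylene and 1 higher in each gas, and the nitrate and phosphate transport median in air was above it (0.21, percentile 99.85). YSL13 was the member that rose in both gases (1.22, 1.97), while NAS1 (-1.48, -2.08) and NAS2 (-1.26, -1.47), over 10-fold brighter in roots, fell. The actin ratio of mhz7 shoots exceeded that of WT by 0.59 in air and 0.71 in ethylene on the log2 scale.

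**Figure D4:**
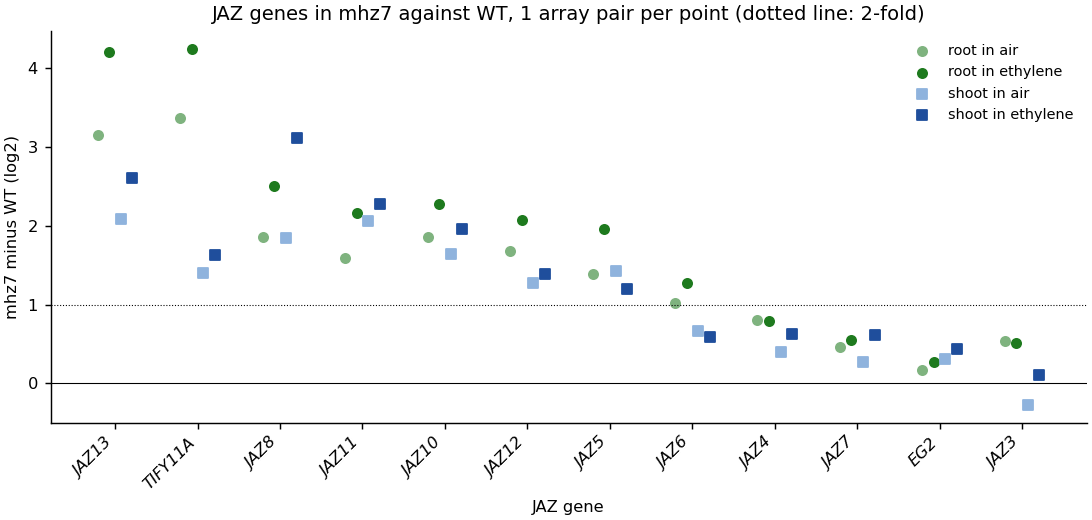
The mhz7 minus WT log2 difference (vertical axis) of the 12 measured JAZ genes (horizontal axis), with 1 point per pair of arrays (circles, root; squares, shoot; light, air; dark, ethylene; the dotted line is 2-fold). The median difference of the 12 genes was 1.49, 2.02, 1.34 and 1.29 in roots in air, roots in ethylene, shoots in air and shoots in ethylene.

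Across the 4 pairs of genotype arrays, limma placed 310 of 21444 probe sets past an adjusted p of 0.05, 190 higher and 120 lower in mhz7, over 219 genes and each in the same direction in 4 of 4 pairs. The jasmonate-related JAZ10 (1.94, SE 0.115, adjusted p = 0.0103) and JAZ11 (2.02, adjusted p = 0.0112), the calmodulin-like gene CML31 (1.52, adjusted p = 0.00955), the 4-coumarate:CoA ligase gene Os4CL5 (0.94, adjusted p = 0.0112) and the chitinase gene Cht2 (1.89, adjusted p = 0.0290) were the higher genes with a symbol and the smallest p. AldC-1 (-0.56), CIPK16 (-0.85), the cystatin gene OC-X (-1.20), the aquaporin gene PIP2-2 (-0.62) and ARGOS (-3.43) were the corresponding lower genes, with adjusted p from 0.0382 to 0.0443. Without regard to symbols, LOC9268308 (4.87), LOC4344089 (2.20) and LOC4352127 (1.85) led the higher genes, and LOC4331847 (-1.15) and LOC9269366 (-1.50) the lower ones.

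Of the 27 jasmonate genes 7 passed in this genotype fit, all higher, and adjusted over the list alone 22 did, 19 higher and 3 lower. Defence genes gave 3, and 8 adjusted over the list alone, all higher. No cell cycle or histone gene passed over all probe sets, while adjusted over the list alone 17 of 39 did, all higher. For ethylene perception and signalling the counts were 1 (EIN2) and 5, and for iron acquisition 0 and 5, of which 4 were lower. The count of 310 rested on having all 4 pairs: it was 9 without the pair of root arrays in air, 18 without shoot in air, 49 without root in ethylene and 5 without shoot in ethylene. It was 173 with a floor of 200, 2 with no signal minimum, 1008 without the pair block and 1523 at an adjusted p of 0.1. Differences of genotype effect between tissues or gases count as error in this fit. The actin ratio was higher in mhz7 in all 4 pairs, by 0.04, 0.45, 0.59 and 0.71 on the log2 scale, so RNA integrity and genotype are not separated in it.

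For ethylene against air over the 4 pairs, limma placed 0 of 21444 probe sets past an adjusted p of 0.05, and 1704 had an unadjusted p under 0.05. In this fit WT and mhz7 differences are averaged, so a difference in WT alone counts partly as error. Adjusted over the list alone, 4 of the 10 diterpenoid phytoalexin genes were lower in ethylene, as were 2 of the 15 nitrate and phosphate transport genes. For CYP701A8 the ethylene effect was -1.25 (SE 0.157), lower in 4 of 4 pairs. The interaction fit, which tests whether the ethylene effect differed between mhz7 and WT by the same amount in root and shoot, also gave 0 probe sets (1304 at an unadjusted p under 0.05). For NSHB2 the interaction was -3.05 (SE 0.200, adjusted p = 0.434) and for ETR2 -0.92 (adjusted p = 0.485). With 1 residual degree of freedom this fit recovered 1 of 100 simulated changes of log2 size 1 and 95 of 100 of size 2. With a variance trend in limma (trend=TRUE) 5 probe sets passed, those of NSHB2 (adjusted p = 0.0358), NSHB1 (-2.66, not from its brightest probe set, which read -1.03), LOC4349647 (2 probe sets, 2.03 and 1.97) and 1 with no gene listed; these were named after their values were seen.

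Shoot against root over the 4 pairs gave 5554 probe sets higher in shoot and 8905 higher in root at an adjusted p of 0.05. The protochlorophyllide reductase genes PORA (5.89) and PORB (6.02), RCABP69 (5.15) and the germin-like gene GER8 (5.26) were higher in shoot, and the Casparian strip gene OsCASP1 (-4.53), GLU5 (-4.76), ADF-1 (-4.81) and EXP3 (-4.19) higher in root. All 17 photosynthesis and chlorophyll genes were higher in shoot, with a median of 4.80. Of 39 cell cycle and histone genes 28 were higher in root and 3 in shoot, and of 26 cytosolic ribosomal protein genes 23 and 3.

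In the remaining lists few members changed. Heat shock proteins, type 2C protein phosphatases, gibberellin genes, cytokinin metabolism and auxin biosynthesis kept their medians inside the middle 95% of random lists in all 8 comparisons of gas or genotype. Cytosolic ribosomal proteins lay above that range in mhz7 against WT in air, in roots (0.09) and in shoots (0.07), and auxin response above it with ethylene in mhz7 roots (0.09) and shoots (0.09) and below it in mhz7 against WT in shoots in air (-0.09). Cytokinin response regulators had medians of -0.13 with ethylene in WT roots, 0.13 in mhz7 shoots and 0.30 in mhz7 against WT roots in ethylene, and none of the 10 changed 2-fold. Ethylene synthesis genes had a median of -0.19 with ethylene in WT roots (percentile 1.3). Other medians outside the range were, with ethylene, those of nitrate and phosphate transport in WT roots (-0.05) and mhz7 shoots (-0.11), iron acquisition in WT shoots (-0.11), and in mhz7 roots jasmonate genes (0.09), expansins (-0.04) and the 3 ERF and DREB genes (0.66). In mhz7 against WT they were those of ERF and DREB genes in roots (2.13 in air, 2.75 in ethylene), expansins in roots in ethylene (-0.14), phenylpropanoid enzymes in shoots (0.13 in air, 0.15 in ethylene), and photosynthesis genes (-0.25) and aquaporins (-0.11) in shoots in air. Germin-like proteins lay below the range in 6 of the 8 comparisons, with the lowest median at -0.25 and GLP2 rising in both WT tissues. Only 3 secretory peroxidase genes were measured, with medians of 0.33 with ethylene in WT shoots, -0.53 in mhz7 shoots, and -0.63 and -0.75 in mhz7 against WT shoots in air and ethylene (percentiles 0.15 and 0.25). PRX112 was lower by at least 3.37-fold with ethylene in WT shoots. Its signal in air there, 337, is the middle value of the 15 root-abundant probe sets, so the gene appears to be 1 of them. The match with their median is therefore no separate evidence. That set went from 3.71% to 1.76% of its root signal in WT shoots. All 3 peroxidase genes were higher in root in the tissue fit. The seed storage and reserve list had 2 measured genes and no median was formed.

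**Figure D5:**
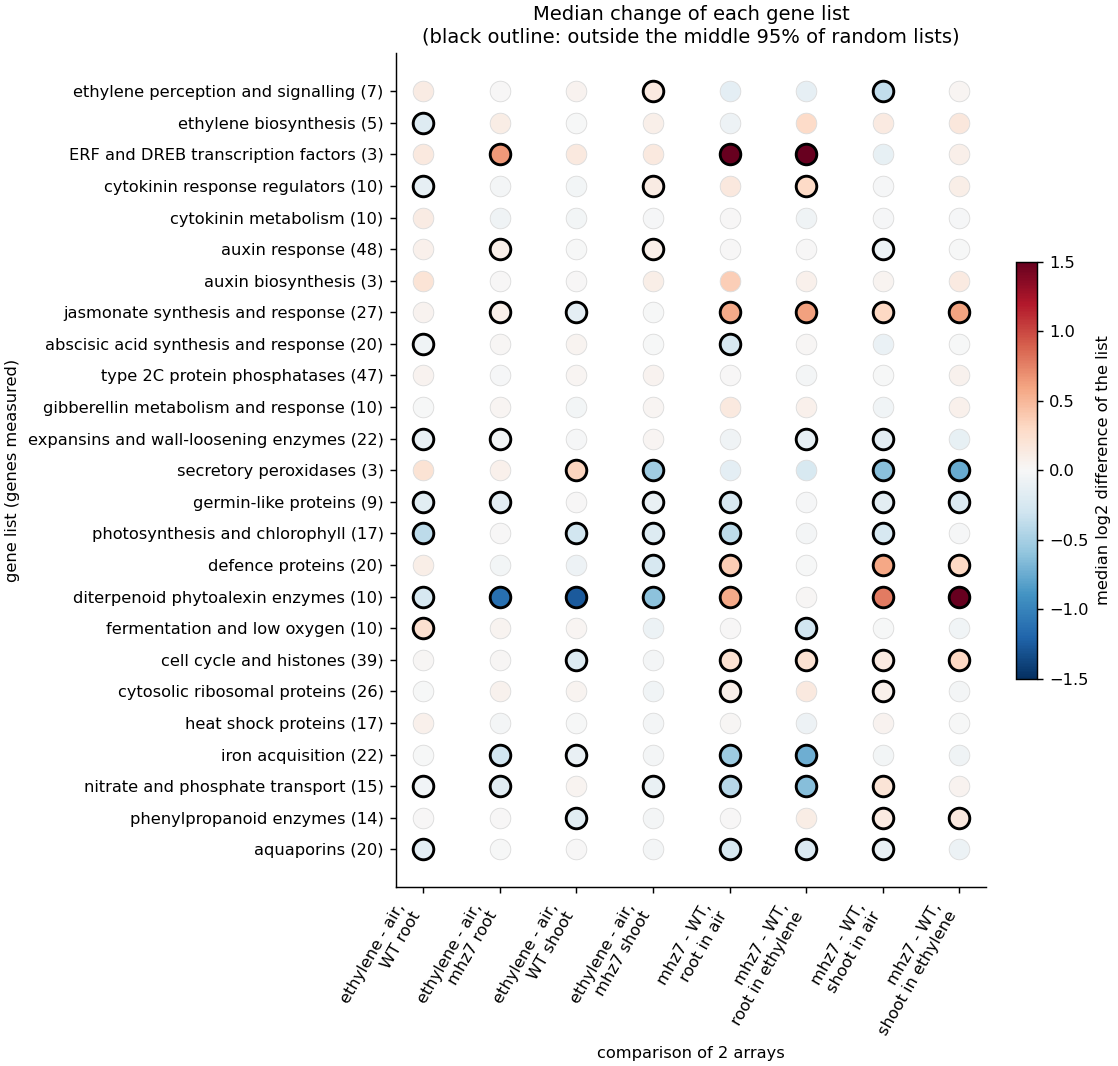
Median log2 difference (colour) of each gene list (vertical axis, number of genes measured in brackets) in the 8 comparisons of 2 arrays (horizontal axis), with a black outline where the median lay outside the middle 95% of 10000 random lists matched on mean signal. The jasmonate list was higher in mhz7 in all 4 genotype comparisons, with medians of 0.56, 0.61, 0.31 and 0.61.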

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

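The tests on differences between the single WT samples, on the sign of the air difference in the same tissue and on RNA integrity were chosen only after the results they address were seen.

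NSHB2 stood out because its ethylene effect differed between the genotypes. It rose in WT roots (1.71) and shoots (1.40), fell in mhz7 shoots (-1.33) and was at most -1.67 in mhz7 roots, where the ethylene signal was at the floor. The difference between the genotypes was tested by limma as an interaction of -3.05 (SE 0.200, adjusted p = 0.434), which does not pass 0.05 over all probe sets. Its same direction in 2 of 2 tissues adds no support. The gene was flagged for opposite ethylene changes in the genotypes in both tissues.

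Ethylene changes of WT were small in mhz7, for example in ADC2, CRSH2, ARGOS and LOC4344999. Compressed fold changes on the mhz7 air arrays would lower the slope of their shoot minus root differences on those of WT. That slope, from the air arrays only, was 0.977 (1.10 as the inverse of the slope of WT on mhz7). The mhz7 ethylene arrays, with actin ratios of 9.32 in root and 13.5 in shoot, were not part of it. Compression on those arrays was therefore not tested. Noise of single probe sets would leave second probe sets of the same genes unmoved, but their WT medians in the direction of the first were 1.02 and 1.05. Chance differences between the single WT samples cannot be told apart from a response, although 14.6% of the WT root changes recurred in WT shoots against at most 2.83% in random sets. By the same measure 12.9% of the WT root changes recurred in mhz7 roots, against at most 2.18% in random sets. Recurrence of the root changes, rises and falls pooled, was thus similar in the other WT tissue and in the mutant. Split by direction, WT root rises recurred at 11.97% in WT shoots and 6.84% in mhz7 roots, and root falls at 17.3% and 19.1%. WT shoot rises recurred at 23.9% in WT roots and 0.855% in mhz7 shoots, and shoot falls at 12.96% in both. Rises thus recurred less in the mutant than in the other WT tissue, and falls did not. The probe sets were also picked for their size in WT, which alone makes their change on other arrays smaller. Ethylene responses that depend on MHZ7 remain possible but are not established with 1 sample per condition.

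Probe sets that rose with ethylene in WT were already lower in mhz7 than in WT in air, with medians of -0.24 in root and -0.54 in shoot. A WT air array read too low would lift this difference, so the sign argues against noise of that array as the cause. With no array shared, WT shoot rises had a median of -0.31 in root air (percentile 0 of random sets) and WT falls one of 0.03 in the other tissue from either side (percentiles 99.99 and 99.12), as an ethylene-type response of WT in air that needs MHZ7 might give. WT root rises had one of 0.00 in shoot air (percentile 58.95), which was set beforehand to count against such a response. Of these rises 38.5% lay below 0 and 38.9% above, a split that no difference would also give. The medians without a shared array thus disagree, and such a response is not settled. ARGOS, which rose in both WT tissues, stood in mhz7 in air at -3.58 in root and -1.91 in shoot.

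Falls outnumbered rises with ethylene in mhz7. Less RNA of the other tissue on the ethylene arrays might lower genes such as TIP2-1 and GER5. Without probe sets at least 10-fold brighter in the other tissue, falls were still 68.0% of the changes in root and 82.4% in shoot, which does not settle it. Lower RNA integrity might also add falls: falls were 49.0% where the ratio of actin moved by 0.04 on the log2 scale, in WT roots, 301 of 418 changes at a shift of 0.38 in WT shoots, 194 of 265 at 0.45 in mhz7 roots, and 114 of 130 at 0.502 in mhz7 shoots. In mhz7 against WT, lower probe sets were 368 of 783 at a shift of 0.04 and 1025 of 1773 at 0.45 in roots. In shoots they were 258 of 667 at 0.59 and 489 of 1114 at 0.71, so falls did not follow the ratio there. Neither less RNA of the other tissue nor lower RNA integrity can be told apart from a response of mhz7 to ethylene.

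Exchanging the array labels within pairs gives too few splits for any share under 0.05. The real grouping gave 310 probe sets for genotype against at most 0 in the other splits (1 of 8 splits reached it) and 14459 for tissue against 0 (1 of 8). For ethylene it gave 0 against 0 (8 of 8), and for the interaction 0 against 0 (2 of 2).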

How the results depend on the processing

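Removal of probe sets brighter in the other tissue was chosen after seeing the data; the other alternatives were fixed earlier. Counts of changed probe sets in the 8 pairs of arrays stayed within 1.5 times with floors of 50 and 200, quantile normalization, loess and that removal, except mhz7 shoot ethylene with a floor of 200 (85 against 130), where fewer weak signals can reach 2-fold. The share of the WT root ethylene changes seen in mhz7 root was 8.25% at 3-fold and 9.21% without probe sets brighter in the other tissue. The share of the WT shoot ethylene changes seen in mhz7 shoot was 5.71% with a floor of 200, 4.42% at 3-fold, 7.08% with 1 probe set per gene and 4.72% without those brighter in roots. The share of the WT root ethylene changes seen in WT shoot was 10.3% at 3-fold. The cause was not tested for these shares. The fit of mhz7 minus WT over 4 pairs gave 173 probe sets with a floor of 200, 2 with no signal minimum (57258 tested), 1523 at an adjusted p of 0.1, 1008 with no pair block and 5 to 49 with a pair left out (fewer arrays). The tissue fit gave 12401 to 13544 and the ethylene fit 0 to 0 with a pair left out. The ethylene by genotype interaction over 2 tissues gave 5 with trend=TRUE. The median of the list photosynthesis and chlorophyll, ethylene minus air, WT root, reversed to 0.0105 over the 3 genes left without probe sets brighter in shoots, since 14 of its 17 genes are left out. Of 200 list medians, 192 stayed inside or outside the middle 95% of random lists with the mean of a gene's probe sets and 188 with quantile normalization, and none changed sign while outside it. Without probe sets brighter in the other tissue 180 stayed, 8 moved inside, 7 moved outside, 1 reversed and the others could not be formed. Of 857 values of named genes in pairs of arrays, 857 stayed under loess and 857 under quantile normalization, 557 with a floor of 200 and 748 with a floor of 50. The share of signals at or below the floor, 51.5 to 53.1%, limits what weak transcripts can show.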

Other observations

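PDC1 changed in different tissues in the 2 genotypes. Its signal was 144 and 151 in WT roots in air and ethylene, 1169 and 119 in mhz7 roots, 1206 and 130.2 in WT shoots and 5543 and 4936 in mhz7 shoots. PDC2, of the same enzyme family, stayed within 2-fold, at 9537 and 12423 in WT roots and 6122 and 6273 in mhz7 roots. The cytokinin activation gene LOGL9 was higher in mhz7 over the 4 pairs (1.55, adjusted p = 0.0475, 4 of 4 pairs). In the interaction fit, adjusted over the list alone, 5 of 22 iron acquisition genes had a lower ethylene effect in mhz7 than in WT, and 0 passed over all probe sets. In the tissue fit 13 iron acquisition genes were higher in root and 4 in shoot, and 12 aquaporin genes were higher in root and 4 in shoot.

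Probe sets of NSHB1 disagreed: with ethylene in WT shoots the brightest read -0.17 and another 1.34. Among changed genes with a second measured probe set, that probe set moved in the same direction in 87.0 to 95.2% of cases. The 3′ to 5′ ratio of the GAPDH control was 4.71 in WT shoots in air and 9.08 in mhz7 shoots in ethylene, and that of ubiquitin 1.35 and 1.73.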
